A study of Solanum dulcamara with 18 samples.

How the data were processed

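The data were RNA-seq read counts from leaves of Solanum dulcamara (bittersweet nightshade), a wild perennial of the tomato and potato family. Plants received 1 of 3 water treatments (control, drought or flooding) for 5 days, and the treatment went on through 2 further days with or without caterpillars. The caterpillars were larvae of Spodoptera exigua, the beet armyworm, a generalist leaf feeder, and they fed for 48 h. Each of the 6 combinations had 3 samples, which the series design describes as biological replicates, for 18 samples in all. Groups and replicate numbers were taken from the sample labels, and table columns were tied to samples through the column numbers that the labels give. Infested and uninfested libraries carry separate runs of these numbers, whose meaning is not stated. A difference in handling that followed them could not be told apart from herbivory.

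Total RNA was extracted with a plant RNeasy kit and treated with DNase, and libraries were made with standard Illumina protocols, per the labels' protocols. Bowtie 0.12.7 and DESeq were named in the submitters' processing notes. The assembly, the counting tool and the use of strand were not given in the sources used here. Features were assembled contigs, 501 to 15047 bases long with a median of 1054 bases, and the deposited tables did not pair them with gene names. None of the contig IDs was found in the reference gene table (0 of 24158), so contigs are identified by ID and length, no genome position is given, and the gene lists fixed before the data were examined were not used. Where a locus gave several contigs, reads could be divided between near-identical copies; 278 contigs came from the 136 assembly components that held more than 1.

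The first deposited table held raw counts of reads per contig for 24158 contigs, of which 546 had 0 counts in all samples. The second deposited table held a normalized signal for 22410 contigs, described by its title as having noise contigs removed. The rule for noise was not given in the sources used here. On the values, each entry of this table equalled the raw count times 1 factor per library, per kilobase of contig, with a largest relative departure of 1.1e-09. The table left out 1748 contigs, of which 134 were among those tested here. Contig length was the only other value in both tables.

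Differential expression was tested on the raw counts with edgeR 4.0.16 in R 4.3.3. Contigs were kept with filterByExpr (minimum count of 10, minimum total of 15), which left 20170 contigs holding a median of 99.923% of each library's reads. Libraries were scaled with TMM, and 1 robust quasi-likelihood model with a mean for each of the 6 groups was fitted to all 18 libraries, leaving 12 residual degrees of freedom. From this model came 7 comparisons of 2 groups, 3 interaction contrasts (differences between water treatments in the response to herbivory) and the herbivory response averaged over the 3 water treatments. A contig was called when the Benjamini-Hochberg adjusted p of the edgeR quasi-likelihood test was under 0.05, and calls with a fold of at least 2 were counted as well. All adjusted p-values of single contigs given in the text come from this test. The SE given with a log2 fold change was derived from it, as the absolute log2 fold change divided by the square root of the F statistic. Levels are in CPM, the count scaled by the TMM-adjusted library size, as mean ± SD of 3 libraries, and log2 CPM used a prior count of 2.

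The size of the herbivory response was compared between water treatments with the contigs called for averaged herbivory, separately for those that rose (the induced set) and those that fell (the repressed set). Each interaction contrast was tested on these sets with camera in limma 3.58.1 (preset correlation of 0.01, and again with an estimated correlation) and with fry. fry asks whether the contigs of a set move on balance in 1 direction, and does not compare them with other contigs. Contigs are not independent replicates, so correlations across contigs carry no p-value. Overlaps of calls are given beside the number expected for independent lists. Comparisons that share libraries are given beside values simulated for unchanged groups that share control libraries, with all libraries drawn anew (20 simulations).

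Contigs named in the text followed a rule set before the data were examined. Among called contigs with a mean of at least 8 CPM, and with all 3 libraries of 1 group above all 3 of the other, the 2 with the largest rise and the 2 with the largest fall were named for each comparison, with no condition on overlap for interactions. Other contigs are described without their ID.

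Library totals ran from 6717218 to 16056241 reads, and the common biological coefficient of variation was 18.6%. All 18 pairs of replicates within a group differed by more than counting noise, with chi-square per degree of freedom between 7.27 and 42.6. With 3 samples against 3, an exact permutation test of a single value cannot go below a two-sided p of 0.1, so single contigs were tested only in the model across all contigs. The test was checked on simulated data. For herbivory in control plants (19795 contigs in that step), 22.4% of contigs changed 1.5-fold, 65.7% of those changed 2-fold and 89.4% of those changed 4-fold were recovered, with 4 false calls among 122. For the drought interaction (19783 contigs), 38.8% of interactions of 2-fold, 73.1% of 4-fold and 86.4% of 8-fold were recovered, with 5 false calls among 137. A small interaction could therefore have been missed.

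The alternatives were DESeq2 1.42.0 on the same counts, RLE size factors, no filter, a stricter filter, only the contigs of the normalized table, limma on the normalized table with pseudocounts of 1 and 5, only the 6 samples compared, the replicate number as a block, sets of the 500 contigs with the smallest p in each direction, and leaving out each of the 18 libraries. Thinning of all libraries to the smallest, removal of a trend on contig length and expression, and leaving out 2 libraries together were added after seeing the data. No sample was left out of the results given first. Where an alternative refitted the model, each set was chosen anew from that fit, so its median is for partly different contigs. Removal of the trend kept the sets of the main fit.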

Results

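Leaf transcriptomes of Solanum dulcamara were measured under control watering, drought and flooding, each with and without 48 h of feeding by Spodoptera exigua caterpillars, with 3 libraries per combination. The series asks how drought and flooding affect the transcriptomic response to the herbivore. Depth differed between groups, with lower means in infested than in uninfested plants under each water treatment. Uninfested libraries held 13102408 ± 4570059 reads in control plants, 12206778 ± 1067764 in drought plants and 12062695 ± 664005 in flooding plants (SD, n = 3 each). Infested libraries held 9547525 ± 784217, 9915308 ± 929071 and 9914708 ± 3764233 reads, respectively (SD, n = 3 each). Within groups, the median SD of a contig's log2 CPM lay between 0.18 and 0.23.

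The first axis separated the libraries by herbivory but also set uninfested drought plants apart, and the second separated control watering from the other treatments. On the first principal component, which held 30.0% of the variance, all 9 infested libraries lay above all 9 uninfested ones, with the lowest infested library at 20.8 and the highest uninfested library at 6.46. Among uninfested libraries, those of drought plants lay closest to the infested side (mean −2.13 ± 7.45), followed by control plants (−42.8 ± 12.0) and flooding plants (−58.9 ± 16.6, SD, n = 3 each). The second component (24.4%) placed the 6 control-water libraries, at 38.7 or higher, above the 12 drought and flooding libraries, at 1.64 or lower.

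**Figure D1:**
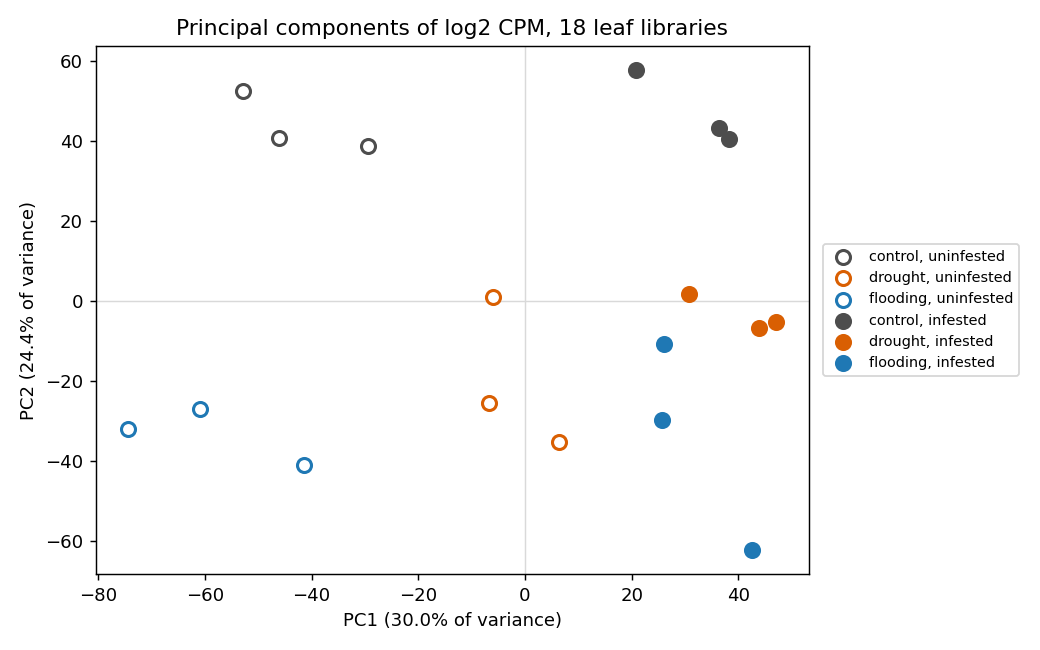
First and second principal components of log2 CPM over the tested contigs, 1 point per library, colored by water treatment, with filled points for infested and open points for uninfested plants. All 9 infested libraries lie at 20.8 or higher on the first component, and the 6 control-water libraries lie at 38.7 or higher on the second.

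Feeding by the caterpillars in control plants raised 1334 contigs and lowered 790 of the 20170 tested, of which 648 rose and 168 fell at least 2-fold. Large changes were nearly all increases, with 102 contigs raised and 1 lowered at least 8-fold. Among contigs named by the rule, comp4088_c0_seq1 (2227 bases) rose from 13.6 ± 4.98 to 1358 ± 1299 CPM (SD, n = 3 each), a log2 fold change of 6.62 ± 0.82 (SE, edgeR adjusted p = 0.000202). The shorter comp521_c0_seq1 (861 bases) rose from 82.3 ± 36.6 to 5655 ± 2412 CPM (log2 fold change 6.10 ± 0.74, adjusted p = 0.000162). In the other direction, comp14844_c0_seq1 (2557 bases) fell from 78.4 ± 16.9 to 11.0 ± 4.17 CPM (−2.84 ± 0.25, adjusted p = 1.13e-05) and comp1461_c0_seq1 (1844 bases) from 129 ± 20.4 to 23.4 ± 10.1 CPM (−2.46 ± 0.41, adjusted p = 0.00163). The spread of the infested libraries was wide for comp4088_c0_seq1, whose log2 fold change was 5.46 without infested control replicate 2. The 3 libraries of each group did not overlap for 6682 of the 20170 contigs (33.1%, against 10% by chance). Among the 2124 called contigs this held for 2090, but the calls rest on the same libraries, so that number is no separate evidence. Without uninfested control replicate 1 or 2 the count of called contigs was 1024 or 937, and without infested control replicate 1 or 2 it was 1252 or 1264.

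In drought plants, herbivory raised 579 contigs and lowered 69, and 319 rose and 26 fell at least 2-fold. Calls were mostly increases here (89.4%, against 62.8% in control plants). The contig with the largest named rise, comp6001_c0_seq1 (834 bases), went from 12.4 ± 3.22 to 440 ± 341 CPM (log2 fold change 5.15 ± 0.60, SE, edgeR adjusted p = 0.000471). comp4088_c0_seq1 rose from 41.4 ± 20.7 to 1337 ± 870 CPM (5.02 ± 0.75, adjusted p = 0.00241). Without infested drought replicate 1 these log2 fold changes were 4.37 and 4.36. comp14844_c0_seq1 fell from 44.3 ± 6.87 to 9.28 ± 1.53 CPM (−2.26 ± 0.25, adjusted p = 0.000275). comp1461_c0_seq1, which was already low in uninfested drought plants at 15.2 ± 8.91 CPM, fell further to 3.27 ± 1.12 CPM (−2.22 ± 0.48, adjusted p = 0.0212). This last call was lost without uninfested drought replicate 2 or 3 or infested drought replicate 1 or 3 (adjusted p = 0.0736, 0.0609, 0.101 and 0.0818), and with only the 6 samples compared (0.124). The number of contigs called was 373 or 226 without uninfested drought replicate 1 or 2, 181 without infested drought replicate 1, and 975 with DESeq2.

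In flooding plants, herbivory raised 1933 contigs and lowered 1167, 1028 and 285 of them at least 2-fold. comp4088_c0_seq1 rose from 8.22 ± 2.23 to 1410 ± 777 CPM (log2 fold change 7.42 ± 0.85, SE, edgeR adjusted p = 5.78e-05). comp673_c0_seq1 (879 bases) rose from 3.81 ± 0.745 to 641 ± 142 CPM (7.38 ± 1.02, adjusted p = 0.000253). comp1461_c0_seq1 fell from 89.2 ± 23.5 to 12.6 ± 0.957 CPM (−2.82 ± 0.42, adjusted p = 0.00047). The abundant comp42_c0_seq1 (1548 bases) fell from 2069 ± 1319 to 304 ± 129 CPM (−2.77 ± 0.50, adjusted p = 0.00184), and its log2 fold change was −2.18 without uninfested flooding replicate 2. The count of 3100 went to 2025 or 1477 without uninfested flooding replicate 1 or 2 and to 1929 without infested flooding replicate 2. A fit of only the 6 samples called 1225, of which 79.9% rose against 62.4% in the full model, while the like fit in control plants called 2393, so the order of the counts of control and flooding plants turned between the fits.

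**Figure D2:**
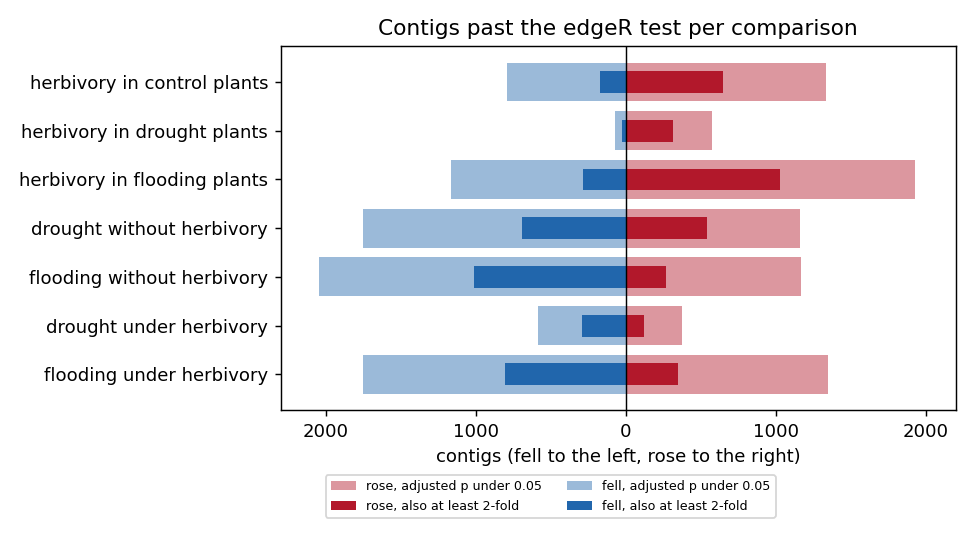
Contigs past the edgeR test (adjusted p under 0.05) in each comparison of 2 groups, with risen contigs to the right of 0 and fallen ones to the left, as pale bars, and those changed at least 2-fold as dark bars. Herbivory raised 1334, 579 and 1933 contigs in control, drought and flooding plants, and flooding without herbivory lowered 2043.

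The herbivory responses of the 3 water treatments, which share no library, overlapped far beyond independent lists. Contigs raised in all 3 numbered 421, against 3.67 expected for independent lists, and contigs lowered in all 3 numbered 35, against 0.156. No contig was called in opposite directions in any pair of water treatments. Of the contigs that rose in control plants, 97.2% had a positive log2 fold change in drought plants and 99.7% in flooding plants. Of those that fell in control plants, 87.9% had a negative one in drought plants and 97.2% in flooding plants. Across contigs, log2 fold changes correlated with r of 0.54 between control and drought plants, 0.76 between control and flooding plants and 0.52 between drought and flooding plants. The 421 went to 270 or 178 without uninfested drought replicate 1 or 2 and to 152 without infested drought replicate 1, and the 35 lay between 11 and 63 over the left-out libraries, furthest below without uninfested drought replicate 2 or infested drought replicate 1 (11 each) and furthest above without uninfested flooding replicate 3 (63). The 35 also went to 17 without infested drought replicate 3, to 16 without uninfested control replicate 2, to 21 without uninfested control replicate 1 or infested control replicate 2, and to 23 without uninfested flooding replicate 1.

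Averaged over the water treatments, herbivory raised 3230 contigs and lowered 2697. Of these, 870 rose and 155 fell at least 2-fold, and 107 rose and 2 fell at least 8-fold. comp4088_c0_seq1 had an average log2 fold change of 6.35 ± 0.47 (SE, edgeR adjusted p = 2.38e-07) and comp521_c0_seq1 one of 5.52 ± 0.42 (adjusted p = 2.42e-07). The largest named falls were those of comp1461_c0_seq1 (−2.50 ± 0.25, adjusted p = 4.48e-06) and comp14844_c0_seq1 (−2.22 ± 0.14, adjusted p = 2.98e-08).

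Single contigs seldom differed detectably between water treatments in their response to herbivory. With edgeR, the drought interaction called 0 contigs (1301 at an unadjusted p under 0.05, where 1008 are expected by chance), and DESeq2 called 33, 27 of them with a lower log2 response in drought than in control plants. The flooding interaction called 0 contigs with edgeR (755 at an unadjusted p under 0.05) and 6 with DESeq2. The direct contrast of flooding against drought plants called 4 contigs with edgeR, all with a higher response in flooding plants (1956 at an unadjusted p under 0.05), and 146 with DESeq2, 129 of them higher in flooding plants. The 4 lay between 1 (without infested drought replicate 2) and 11 (without uninfested control replicate 3) over the left-out libraries, and were 7 with a stricter filter and 10 with limma on the normalized table at a pseudocount of 1. comp5067_c0_seq1 (1787 bases) rose under herbivory from 0.886 ± 0.383 to 15.0 ± 1.49 CPM in flooding plants and from 15.6 ± 1.09 to 28.9 ± 3.76 CPM in drought plants, a difference in log2 response of 3.18 ± 0.33 (SE, adjusted p = 0.000672). comp21469_c0_seq1 (1064 bases) went from 1.10 ± 0.646 to 45.2 ± 0.708 CPM in flooding plants and from 8.66 ± 2.38 to 40.6 ± 5.46 CPM in drought plants (3.13 ± 0.42, adjusted p = 0.0135). The other 2 were contigs of 1144 and 718 bases, with differences of 2.27 ± 0.33 (adjusted p = 0.0261) and 2.57 ± 0.40 (adjusted p = 0.045). In all 4, the mean of uninfested flooding plants lay below that of uninfested drought plants. Only comp5067_c0_seq1 stayed past the threshold without each of the 18 libraries, and comp21469_c0_seq1 missed it without infested drought replicate 2 (adjusted p = 0.0656).

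**Figure D3:**
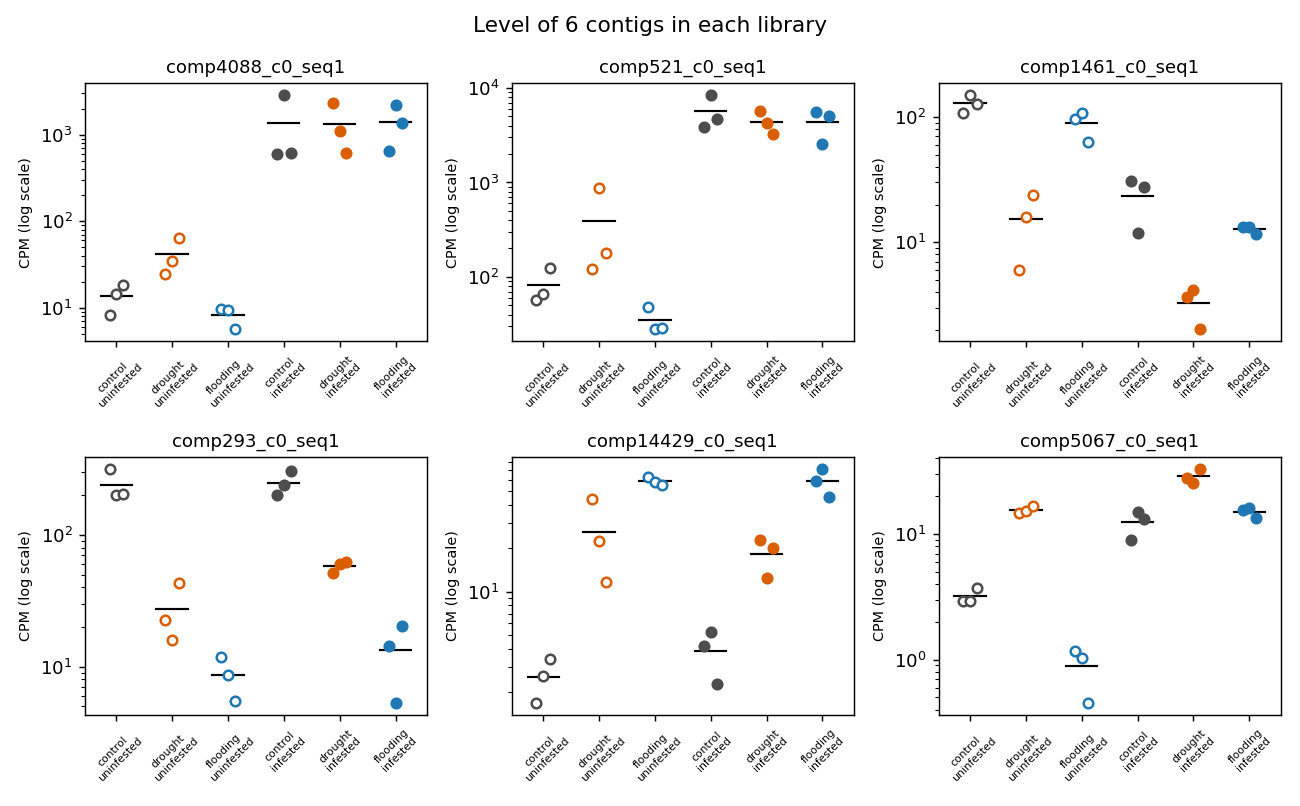
Level of 6 contigs in CPM on a log axis, 1 point per library and a bar at the mean of each group of 3, with uninfested plants as open points and infested plants as filled points. The contig comp5067_c0_seq1 had 0.886 CPM in uninfested flooding plants and 15.6 CPM in uninfested drought plants, and comp293_c0_seq1 was lower in drought and flooding plants than in control plants with or without caterpillars.

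As a set, the contigs induced by herbivory had a smaller median response in drought than in flooding plants, with chance regrouping not excluded. When drought and flooding labels were exchanged, 9 of 100 splits gave a median difference as large, the real one included. The 3230 induced contigs had a median log2 fold change of 0.43 in drought, 0.58 in control and 0.69 in flooding plants. The median difference between flooding and drought plants was 0.27, with 80.0% of contigs higher in flooding (camera adjusted p = 5.52e-21, adjusted p = 0.0287 with an estimated correlation, fry adjusted p = 0.0115). Between drought and control plants it was −0.17 (camera adjusted p = 6.62e-13, adjusted p = 0.0862 with an estimated correlation, fry adjusted p = 0.112), and −0.11 without uninfested drought replicate 3. Between flooding and control plants it was 0.10 (camera adjusted p = 0.000222, adjusted p = 0.249 with an estimated correlation, fry adjusted p = 0.169). Its median was 0.034, 0.062 and 0.065 without uninfested control replicate 3, infested control replicate 3 and uninfested flooding replicate 2, respectively. In these fits the unadjusted camera p was not under 0.05. With the 500 contigs of smallest p in place of the 3230, the medians were 0.55 for flooding minus drought, −0.33 for drought minus control and 0.25 for flooding minus control. The 2697 repressed contigs had medians of −0.22 in drought, −0.47 in control and −0.49 in flooding plants. Their difference between drought and control plants was 0.23 (camera adjusted p = 4.31e-15, adjusted p = 0.141 with an estimated correlation, fry adjusted p = 0.114). Between flooding and drought plants it was −0.25 (camera adjusted p = 3.02e-19, adjusted p = 0.0997 with an estimated correlation, fry adjusted p = 0.112). Between flooding and control plants it was −0.027 (camera adjusted p = 0.0258, adjusted p = 0.608 with an estimated correlation, fry adjusted p = 0.917), and it changed sign without uninfested control replicate 3, infested control replicate 3 or uninfested flooding replicate 2 (0.031, 0.036 and 0.048). Without infested flooding replicate 2 the median was −0.0012 and the unadjusted camera p was not under 0.05. The median was −0.17 without uninfested flooding replicate 3 and −0.059 with the 500 contigs of smallest p. In these adjusted values, 10 set results formed the family.

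The levels of the induced set differed more among uninfested than among infested plants. Relative to uninfested control plants (0 ± 0.0886), its mean log2 CPM was 0.162 ± 0.0437 in uninfested drought plants and −0.333 ± 0.128 in uninfested flooding plants, and the 3 libraries of each of these groups lay apart from those of the other. Infested plants had 0.809 ± 0.0719 under control watering, 0.749 ± 0.092 under drought and 0.654 ± 0.0502 under flooding (SD, n = 3 each). The repressed set stood at −0.231 ± 0.0268 in uninfested drought plants and 0.0218 ± 0.189 in uninfested flooding plants, and at −0.54 ± 0.0776, −0.524 ± 0.0765 and −0.541 ± 0.0888 in infested control, drought and flooding plants.

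**Figure D4:**
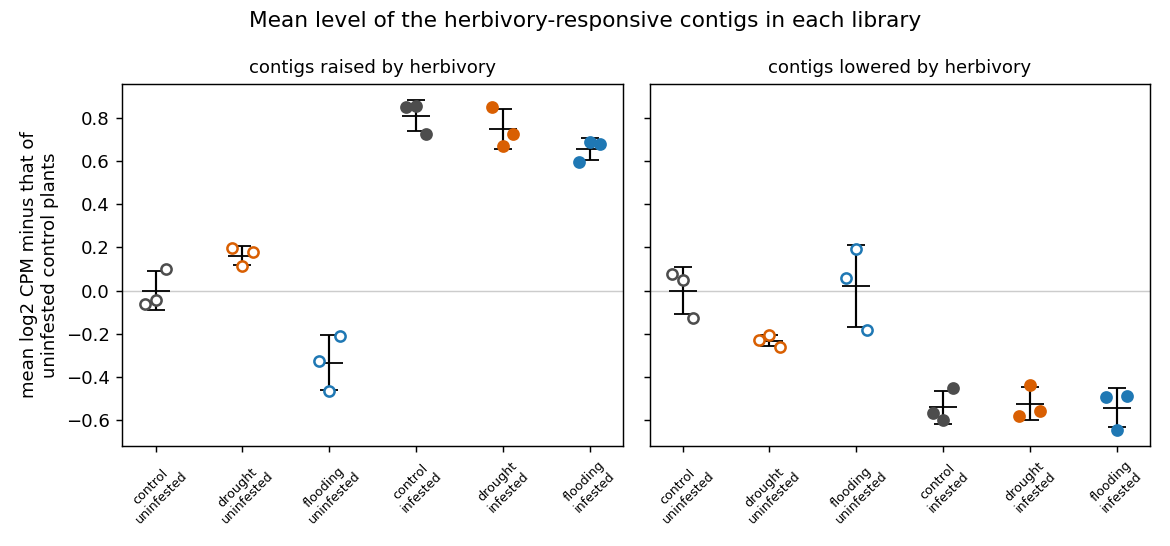
Mean log2 CPM of the contigs raised (left) and lowered (right) by averaged herbivory, minus the mean of uninfested control plants, with 1 point per library and bars at the mean ± SD of 3 libraries. Raised contigs stood at 0.162 in uninfested drought plants and at −0.333 in uninfested flooding plants, against 0.654 to 0.809 in the infested groups.

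Drought without herbivory raised 1160 contigs and lowered 1750, 540 and 689 of them at least 2-fold. Among the falls, comp22145_c0_seq1 (711 bases) fell from 26.9 ± 10.7 to 2.99 ± 1.12 CPM (log2 fold change −3.16 ± 0.40, SE, edgeR adjusted p = 0.000363) and comp293_c0_seq1 (986 bases) from 241 ± 66.3 to 27.3 ± 14.2 CPM (−3.15 ± 0.43, adjusted p = 0.00053). The size of the largest named rises rested on 1 library. comp9050_c0_seq1 (656 bases) rose from 1.05 ± 0.35 to 120 ± 180 CPM (6.87 ± 1.22, adjusted p = 0.0026) and comp7122_c0_seq1 (918 bases) from 0.668 ± 0.166 to 41.5 ± 66.9 CPM (5.90 ± 1.34, adjusted p = 0.0102). Without uninfested drought replicate 1, which held 328 and 119 CPM of them, the log2 fold changes were 4.01 and 2.05, and both calls held, as they did without each of the other libraries. Both were lost with only the 6 samples compared (adjusted p = 0.0873 and 0.154). The total of 2910 calls was 1505 or 1617 without uninfested control replicate 1 or 2 and 1534 or 1620 without uninfested drought replicate 1 or 2.

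Flooding without herbivory raised 1170 contigs and lowered 2043, and falls prevailed among the larger changes, with 271 contigs raised and 1014 lowered at least 2-fold. comp293_c0_seq1 fell here too, to 8.66 ± 3.13 CPM (log2 fold change −4.80 ± 0.47, SE, edgeR adjusted p = 5.15e-05), and comp1670_c0_seq1 (2076 bases) fell from 200 ± 43.6 to 8.05 ± 3.90 CPM (−4.64 ± 0.36, adjusted p = 1.77e-05). comp3662_c0_seq1 (974 bases) rose from 1.43 ± 0.144 to 40.9 ± 17.2 CPM (4.82 ± 0.82, adjusted p = 0.0017) and comp14429_c0_seq1 (657 bases) from 2.55 ± 0.855 to 58.5 ± 3.62 CPM (4.45 ± 0.45, adjusted p = 5.15e-05). The total of 3213 calls was 1953 without uninfested control replicate 1.

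Among infested plants, drought raised 378 contigs and lowered 583, 121 and 292 of them at least 2-fold. comp654_c0_seq1 (777 bases) was at 160 ± 84.2 CPM in infested drought plants and 5.80 ± 4.94 CPM in infested control plants (log2 fold change 4.78 ± 0.68, SE, edgeR adjusted p = 0.00196), and comp21833_c0_seq1 (511 bases) at 29.1 ± 14.1 and 2.84 ± 2.97 CPM (3.34 ± 0.80, adjusted p = 0.0304). comp5392_c0_seq1 (869 bases) fell to 4.51 ± 1.85 from 44.4 ± 5.42 CPM (−3.31 ± 0.35, adjusted p = 0.000541), and comp3503_c0_seq1 (510 bases) to 4.03 ± 0.524 from 39.6 ± 3.77 CPM (−3.30 ± 0.33, adjusted p = 0.000517). The call of comp21833_c0_seq1 was lost without infested control replicate 1 or 3 or infested drought replicate 1 or 3 (adjusted p = 0.106, 0.126, 0.061 and 0.11). Without infested control replicate 2, the log2 fold changes of comp654_c0_seq1 and comp21833_c0_seq1 were 5.76 and 4.68. The 961 calls were 392 or 302 without infested control replicate 1 or 3, 347, 483 or 332 without infested drought replicate 1, 2 or 3, and 1534 with DESeq2.

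Among infested plants, flooding raised 1352 contigs and lowered 1750, 347 and 804 of them at least 2-fold. comp262_c0_seq1 (1254 bases) fell from 71.7 ± 25.7 to 2.85 ± 1.90 CPM (log2 fold change −4.52 ± 0.37, SE, edgeR adjusted p = 1.37e-05) and comp223_c0_seq1 (1748 bases) from 1039 ± 712 to 48.9 ± 26.1 CPM (−4.40 ± 0.72, adjusted p = 0.00164). Their log2 fold changes were −5.19 without infested flooding replicate 3 and −3.68 without infested control replicate 3, respectively. comp13011_c0_seq1 (647 bases) was at 58.9 ± 65.8 against 1.45 ± 0.238 CPM (5.34 ± 1.48, adjusted p = 0.0258), a call lost without infested flooding replicate 2 or any 1 of the 3 infested control libraries (adjusted p = 0.13, 0.0748, 0.0691 and 0.0937) and with only the 6 samples compared (0.0519). comp6986_c0_seq1 (1243 bases) was at 84.4 ± 90.2 against 2.89 ± 1.34 CPM (4.87 ± 1.06, adjusted p = 0.00785), a call lost with only the 6 samples compared (0.0545). Without infested flooding replicate 2 the log2 fold changes of these 2 contigs were 3.88 and 3.55, the second with an adjusted p of 0.0458. The 3102 calls were 1405 without infested flooding replicate 2, 1600 without infested control replicate 3 and 1620 with only the 6 samples.

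Responses to water treatment in uninfested and in infested plants, measured in separate libraries, went the same way. Drought raised 221 contigs in both (21.7 expected for independent lists) and lowered 433 in both (50.6 expected), with no contig called in opposite directions and r of 0.61 across contigs. Flooding raised 663 in both (78.4 expected) and lowered 1262 in both (177 expected), 1 contig was called in opposite directions, and r was 0.73.

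Drought and flooding without herbivory shared calls in both directions, 415 raised by both (67.3 expected for independent lists) and 893 lowered by both (177 expected). Another 30 contigs rose under drought and fell under flooding (117.5 expected), and 5 did the reverse (101.5 expected). The correlation across contigs was 0.57. Simulated unchanged groups that shared 3 control libraries, with all libraries drawn anew, gave a mean of 0.51. They also gave 0 shared calls, but without real change hardly any call can arise. That 0 therefore does not measure what shared controls add to the overlap of calls. The covariance of the log2 fold changes was 0.267, against 0.0602 in the simulations, a difference of 0.207. The 3 control libraries could not be split into parts of at least 2. Drought in uninfested plants against flooding in infested plants would share no library, but the overlap of that pair was not computed. Part of the excess may therefore come from the shared controls.

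Water treatment alone was then set against herbivory. Against the herbivory response of control plants, with which it shares the uninfested control libraries, drought without herbivory had r of 0.46 across contigs (0.49 simulated for unchanged groups). The simulated r comes from noise in shared libraries alone, so it does not rank the likeness of real responses. Contigs of like sign were 61.4% (66.4% simulated), and the covariance was 0.212 (0.0594 simulated, difference 0.153). Both raised 271 contigs (76.7 expected for independent lists) and lowered 212 (68.5 expected). Contigs raised by drought and lowered by herbivory numbered 15 (45.4 expected), and 58 did the reverse (115.7 expected). Against the same herbivory response, flooding without herbivory had r of −0.0019 (0.49 simulated), 48.1% of like sign (66.5% simulated) and a covariance of −0.00082 (0.0583 simulated, difference −0.0591). Here 52 contigs were raised by both (77.4 expected) and 69 lowered by both (80.0 expected). Contigs raised by flooding and lowered by herbivory numbered 72 (45.8 expected), and 341 did the reverse (135.1 expected). In comparisons without a shared library, the 1933 contigs raised by herbivory in flooding plants had a median log2 change of 0.14 under drought alone, with 333 raised and 127 lowered (camera adjusted p = 0.000117, adjusted p = 0.249 with an estimated correlation, fry adjusted p = 0.123). With the set chosen anew, the median was 0.070 without infested flooding replicate 2, where the unadjusted camera p was not under 0.05. It was 0.22 without uninfested control replicate 3 or infested flooding replicate 3, again with the set chosen anew. The 1167 contigs lowered by herbivory in flooding plants had a median of −0.31 under drought alone, with 31 raised and 300 lowered (camera adjusted p = 9.57e-13, adjusted p = 0.249 with an estimated correlation, fry adjusted p = 0.0424). Under flooding alone the direction was opposite to herbivory. The 579 contigs raised by herbivory in drought plants had a median of −0.48, with 6 raised and 204 lowered (camera adjusted p = 1.6e-15, adjusted p = 0.0997 with an estimated correlation, fry adjusted p = 0.00318). The 69 lowered by herbivory in drought plants had a median of 0.36, with 23 raised and 2 lowered (camera adjusted p = 5.98e-10, adjusted p = 0.0997 with an estimated correlation, fry adjusted p = 0.0046). The lowered set chosen anew without uninfested drought replicate 2 had a median of 0.23. Across all contigs, r was 0.39 between drought alone and herbivory in flooding plants, and −0.26 between flooding alone and herbivory in drought plants.

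**Figure D5:**
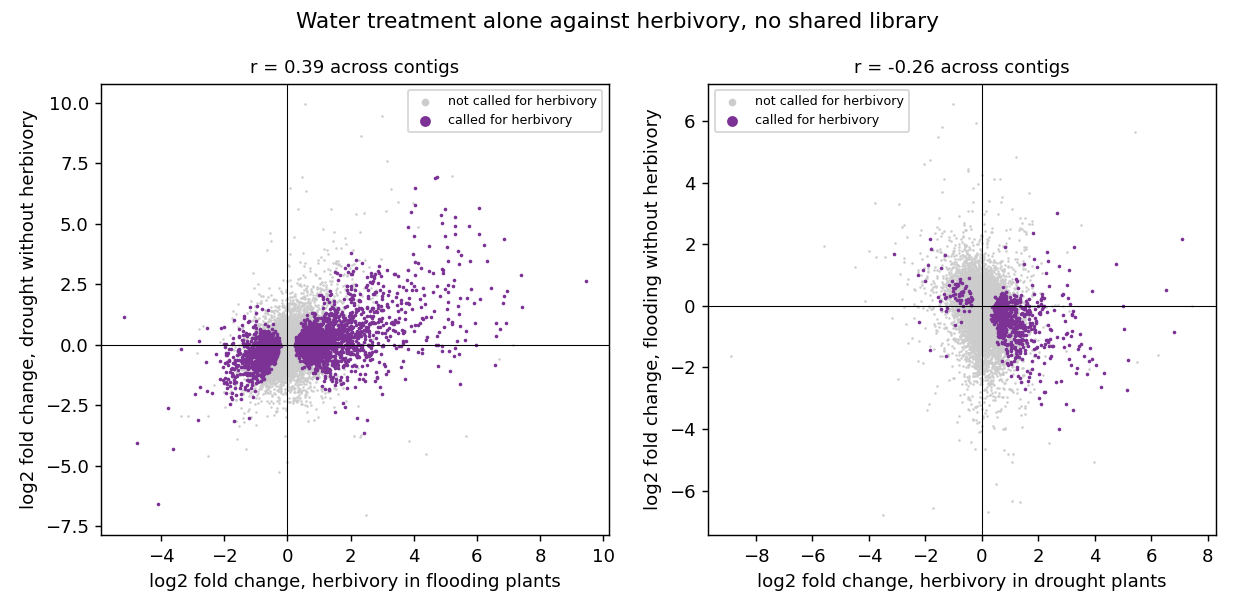
Log2 fold change of each tested contig under drought alone against herbivory in flooding plants (left) and under flooding alone against herbivory in drought plants (right), with contigs called for that herbivory response in purple and the others in gray. The pairs share no library, and r across contigs was 0.39 on the left and −0.26 on the right.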

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

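The tests of library depth, contig length, single libraries and uninfested levels given here were chosen after the result was seen, as were the comparison of splits with equal exchange and the count within the induced set. The regrouping of labels and both tests on DESeq2 were written before.

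The response to herbivory of the 3230 induced contigs differed between flooding and drought plants in the set tests of the difference itself, though regrouping of the labels left chance open. Its median log2 difference was 0.27 between flooding and drought plants (camera adjusted p = 5.52e-21, adjusted p = 0.0287 with an estimated correlation, fry adjusted p = 0.0115). Against control plants, camera alone passed the threshold after adjustment, with −0.17 for drought (camera adjusted p = 6.62e-13, adjusted p = 0.0862 with an estimated correlation, fry adjusted p = 0.112) and 0.10 for flooding (camera adjusted p = 0.000222, adjusted p = 0.249 with an estimated correlation, fry adjusted p = 0.169). For the 2697 repressed contigs the median difference between flooding and drought plants was −0.25 (camera adjusted p = 3.02e-19, adjusted p = 0.0997 with an estimated correlation, fry adjusted p = 0.112). The adjustment was over 10 set results.

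For the largest of these, the difference of 0.27 in the induced set, the tables argued against 3 technical explanations as the whole cause. The median was 0.27 with all libraries thinned to the smallest, 0.30 with a trend on contig length and expression removed, and no lower than 0.22 without any 1 of the 18 libraries. The set was chosen anew in the thinned fit and in each fit with a library left out. Drought plants lay above flooding plants in the mean log2 CPM of the set by 0.495 without caterpillars and by 0.095 with them, and the second gap works against a higher response in flooding plants, so the difference in response may follow from the levels without feeding. Chance regrouping stayed open, and by the rule written in advance the splits went with it. On group means of log2 CPM, 9 of 100 splits that exchanged drought and flooding labels within infested and within uninfested plants gave a median as large as the real 0.255, the real one included, and the highest other was 0.382 in absolute value. Of the 9, 7 exchanged unequal numbers of libraries among infested and uninfested plants, which carries the water effect itself into the contrast, and among the 48 splits with equal exchange 2 were as large, the real one included.

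Contigs whose response differed between flooding and drought plants in the edgeR test were comp5067_c0_seq1 (log2 difference 3.18), comp21469_c0_seq1 (3.13) and contigs of 1144 bases (2.27) and 718 bases (2.57). Of the 40 splits drawn for this contrast, 3 gave 4 or more calls, the real one included, with up to 25 in another split, so chance is not excluded for the count. The drought and flooding interactions called 0 contigs with edgeR (1301 and 755 had an unadjusted p under 0.05, and DESeq2 called 33 and 6). Any split gives 0 or more calls, so the 40 of 40 splits that did so for each say nothing about chance. Other splits reached 551 and 27 calls, and the structure of the samples to which they point may be the water treatment itself. Calls appeared in 3 of the 25 splits of each that exchanged unequal numbers of libraries among infested and uninfested plants, which carries the water effect into the contrast, and in 0 of the 14 that exchanged equal numbers.

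DESeq2 called 146 contigs for the contrast of flooding against drought plants where edgeR called 4. All of them (100%) had an unadjusted edgeR p under 0.05 in the same direction and 121 belonged to the induced set. They may be contigs that fell short of the adjusted threshold in edgeR. Both tools tested the same counts, however, so false calls would tend to share this too. The 100% therefore does not tell true calls from false ones. Counts simulated without any interaction gave at most 11 DESeq2 calls in 5 simulations for this contrast. Their means came from a fit of water treatment plus herbivory, and their dispersions from edgeR. The simulations held the 20170 tested contigs, whereas the real DESeq2 fit held all 24158, so the contig sets differ. For the drought interaction DESeq2 called 33, against at most 7 simulated, and for the flooding interaction 6, which is no more than the simulated maximum of 7. For the contrast of flooding against drought plants, 11 is under 0.1 of the 146, the bound set in advance against false calls as the cause, but the simulations leave out the structure of the real libraries: in these, a split that exchanged equal numbers of drought and flooding labels among infested and uninfested plants gave 25 edgeR calls, against 4 for the real one. An excess of false calls in the real counts therefore remains open.

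For comparisons of 3 libraries against 3, the 10 possible splits are too few for a share under 0.05. The real split and the highest of the others called 2124 and 0 contigs for herbivory in control plants, 648 and 0 in drought plants, 3100 and 79 in flooding plants, 2910 and 0 for drought and 3213 and 0 for flooding without herbivory, and 961 and 0 for drought and 3102 and 0 for flooding under herbivory. For herbivory averaged over the water treatments, the real split called 5927 contigs and the highest of the other splits drawn called 0. Only 1 of 60 splits was as large, the real one, which argues against chance but is the lowest share that 60 splits can give. Splits that mix infested with uninfested libraries add the herbivory effect to the spread, so the gap of 5927 to 0 says nothing beyond that share.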

How the results depend on the processing

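Alternatives that left out 2 libraries, thinned the reads or removed a trend were chosen after seeing the data. Over the 23 counts and set results, 232 of 265 values under alternatives other than leaving out 1 library kept their direction and side of the threshold, or lay within 1.5 times the count, and 357 of 414 did with 1 library left out. For the 40 contig results, 417 of 428 and 687 of 720 did, and none reversed. For sets, the threshold was an unadjusted p under 0.05, from camera at the preset correlation unless another set test is named. With the trend removed no test was rerun, and those values were judged on the direction and size of the median alone. RLE size factors, no filter, the authors' contig list and a pseudocount of 5 on the normalized table kept each count within 1.5 times and each set call, and RLE moved the repressed set, flooding minus control, from −0.0273 to −0.0474. The 500 contigs of smallest p per direction kept each set call with medians of 0.55, −0.33 and 0.25 (induced, flooding minus drought, drought minus control and flooding minus control), against 0.27, −0.17 and 0.10, and of −0.29, 0.24 and −0.059 (repressed). The cause of the changes below was not tested, except that fits of fewer samples have fewer residual degrees of freedom.

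DESeq2 called 975 contigs for herbivory in drought plants, 1534 for drought under herbivory, 33, 6 and 146 for the drought, flooding and flooding-against-drought interactions, and 82 lowered by herbivory in all 3 water treatments. The last interaction gave 7 calls with a stricter filter and 10 with limma on the normalized table at a pseudocount of 1. Fits of the 6 samples compared called 344 (herbivory in drought), 1225 (herbivory in flooding) and 1620 (flooding under herbivory). An adjusted p in 1 water treatment with an unadjusted p in the others gave 1105 contigs raised and 280 lowered in all 3. Thinning gave 2 calls for the drought interaction. Without uninfested drought replicate 1 and infested flooding replicate 2, 2 libraries chosen after results were seen, calls were 392 and 1992 for herbivory in drought and flooding plants, 1880 for drought without herbivory, 1482 for flooding under herbivory and 17 for the flooding-against-drought interaction.

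Before adjustment over the 10 set results, camera with an estimated correlation lost its call at medians of 0.10 (induced, flooding minus control), 0.23 and −0.0273 (repressed, drought and flooding minus control), and 0.14 and −0.31 (raised and lowered by herbivory in flooding plants, under drought alone). fry missed the threshold for the first 4 of these and for −0.17 (induced, drought minus control) and −0.25 (repressed, flooding minus drought). After adjustment, camera with an estimated correlation kept only the induced set, flooding minus drought. The repressed set, flooding minus control, also missed it with a replicate block (−0.0204), after thinning (−0.0318) and without the 2 libraries (−0.0125), and reversed without uninfested control replicate 3 (0.0311), infested control replicate 3 (0.036) or uninfested flooding replicate 2 (0.0479).

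With 1 library left out, calls ranged from 937 to 2514, 181 to 728 and 1477 to 4464 for herbivory in control, drought and flooding plants, from 1505 to 3230 and 1953 to 3397 for drought and flooding alone, from 302 to 1137 and 1405 to 3319 for drought and flooding under herbivory, and from 0 to 2, 0 to 1 and 1 to 11 for the drought, flooding and flooding-against-drought interactions. Contigs raised or lowered in all 3 ranged from 152 to 454 and from 11 to 63. Medians ranged from 0.0344 to 0.14 (induced, flooding minus control), −0.17 to 0.0479 (repressed, flooding minus control) and 0.0698 to 0.22 (raised by herbivory in flooding plants, under drought alone).

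Samples share a replicate number without any stated link, and no clear pairing by number was seen. Deviations of same-numbered samples correlated with a median r of 0.0133 over 45 pairs (−0.321 to 0.394, 10 pairs over 0.1), and 9 of 18 samples correlated best with their own number. No value for unpaired samples was computed beside these, so a weak pairing is not excluded. With the replicate number as a block, calls were 1949, 595 and 2827 for herbivory in control, drought and flooding plants, and the block moved no count by over 1.5 times. At this depth and spread, an interaction of 2-fold in the drought contrast was recovered for 38.8% of simulated contigs, so a lack of calls does not show a lack of interactions.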

Other observations

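The tests of depth, contig length and left-out libraries on the flooding shift were chosen after the result was seen, and the test on contigs of low level was written before.

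The contigs raised at least 8-fold by averaged herbivory were few but took a visible share of the leaf reads. These 107 contigs held 0.115 ± 0.0466% of the reads in uninfested control plants, 0.393 ± 0.158% in uninfested drought plants and 0.0479 ± 0.0222% in uninfested flooding plants. In infested plants they held 2.12 ± 0.729%, 2.13 ± 0.486% and 2.04 ± 0.286% under control watering, drought and flooding (SD, n = 3 each). Most of the share in infested plants lay in 10 contigs, with 1.85 ± 0.725%, 1.87 ± 0.466% and 1.80 ± 0.298%. The contigs were chosen on these libraries, so the rise under herbivory is not independent evidence. The most abundant contig of the leaf, of 930 bases, had a mean of 24816 CPM in uninfested control plants and 8807 CPM in infested flooding plants.

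Contigs that moved in opposite directions under the water treatments were all contigs called for averaged herbivory. All 30 that rose under drought and fell under flooding were in the induced set (4.8 expected for independent lists). Of the 5 with the reverse pattern, 4 were in the repressed set and 1 in the induced set. The sets were called on the same uninfested libraries, in which a rise in drought plants works against membership of the induced set and a fall in flooding plants works for it. No value for unchanged contigs in these shared libraries was computed, so the overlap is not independent evidence of a link.

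Reads in infested libraries alone were found for 160 contigs, which held 598 reads together, and each of them had reads in at most 7 of the 9 infested libraries. Reads in uninfested libraries alone were found for 175 contigs, with 448 reads.

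The contigs raised by herbivory in drought plants were lower under flooding alone. Their median log2 change was −0.48 (camera adjusted p = 1.6e-15, adjusted p = 0.0997 with an estimated correlation). The herbivory comparison that chose them and the flooding comparison share no library. The calls came from the model of all 18 libraries, however, so the choice was not fully independent of the flooding libraries. Of the technical explanations, depth was argued against by a median of −0.50 with all libraries thinned to the smallest and the set chosen anew. A trend on contig length and expression was argued against by −0.44 with it removed. A few abundant contigs taking up reads would have moved all contigs of low level alike. Yet the 98 set contigs under 10 CPM in each group lay −0.622 from the 7230 others in this range (bootstrap 95% interval over contigs −0.856 to −0.379). The interval takes contigs as independent, while their estimated correlation over the whole set was 0.155. It is therefore too narrow and does not measure the spread between libraries. On mean log2 CPM the gap stayed between −0.461 and −0.337 without any 1 of the 6 libraries. Whether the leaves responded to flooding in a way that lowers these contigs before any feeding stays open. With the set chosen anew each time, the median was −0.39 or lower without each of the 18 libraries. No single library therefore made the shift, but any cause shared by the flooding libraries would give this too.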
